A study of Mus musculus with 24 samples.

How the data were processed

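Total RNA of the gastric antrum of mice aged 4 weeks was measured on an Illumina mouse bead array in 24 samples, 1 array each. The mice were wild type or gp130F/F, and were kept specific pathogen free (SPF) or germ-free. Of the 24 arrays, 19 carry a mixed strain label and 5 a BL6 label. Groups were taken from the genotype, housing and strain labels. The title of 1 gp130F/F germ-free array lacks the word BL6 while its strain label gives BL6, and it was counted as BL6.

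The deposited unnormalized table holds 1 signal intensity per probe and array, from -111.1 to 69826, and its values below 0 show that a background had been subtracted from it. Beside each intensity the deposited table gives a detection p-value of the probe relative to the negative controls of the same array. A second deposited table holds log2 values that the authors normalized with neqc of limma on all 24 arrays, which means background correction, quantile normalization between arrays and the log2 scale. The version of limma, the scanner and the export software that the authors used are not given in the sources used here.

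The deposited intensities and detection p-values were processed with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16. The result differed from the deposited log2 values by at most 5e-09, and each of the 24 arrays matched itself best. The array has 45281 probes. Of these, 34885 carry 1 gene symbol, 18 carry several and 10378 carry none. The symbols were compared by Entrez ID with a RefSeq table of the mouse genome for 34807 probes and 0 of them changed. Probes with several symbols were not used. A probe was kept when its detection p was under 0.05 on at least 4 of the 19 mixed-strain arrays, which left 21304 probes, and each gene was read from the probe that was brightest on average. The test covered 15067 genes, of which 11678 have a symbol and 3389 are probes without one, each counted as a gene.

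A linear model with 1 mean per group was fitted with limma (lmFit and eBayes) to the 19 mixed-strain arrays. The 5 BL6 arrays entered the normalization and no comparison, as the series describes. All groups shared 1 estimate of the spread, with 15 residual and 2.85 prior degrees of freedom. Comparisons were gp130F/F against wild type in SPF mice, the same in germ-free mice, germ-free against SPF in wild-type mice, the same in gp130F/F mice, and the difference of the genotype effect between the housing conditions. The p-values are two-sided, are adjusted by the Benjamini-Hochberg method within a comparison, and count as past the threshold under 0.05. They measure the spread between samples, which may be technical, as the labels do not say that samples are separate animals. The comparison of groups in SPF and germ-free mice uses separate arrays, while each housing comparison shares arrays with the genotype comparisons.

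For the size of the genotype effect under the 2 housing conditions, genes were taken that passed the threshold for the effect averaged over both conditions. This choice favours neither condition only where the spread is alike in both. For 41 gene lists of cell types, tissues and pathways, camera of limma compared each list with all other genes in each comparison, two-sided, with a preset inter-gene correlation of 0.01, and a second time with the correlation estimated from the data. Adjustment ran over the 41 lists. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Where a probe was detected on no array of a group, the fold between 2 groups is given as a lower limit relative to the detection limit of the arrays. Where only some arrays of a group detected it, the log2 difference is given as fitted, with the number of arrays, and its size depends on the background. A difference of the genotype effect between housing conditions has no such limit and is given as fitted, with the undetected groups named.

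The groups, tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule names the 10 largest rises and the 10 largest falls among named genes past the threshold of each comparison, up to 4 members with the smallest p of each list discussed, and 12 fixed genes. The fixed genes are Il6st, Stat3, Socs3, Il11, Reg3b, Reg3g, Tff1, Gkn1, Gkn2, Muc5ac, Gast and Tlr2. Of these 11 are measured, and Tff1 is not analysed here.

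On simulated arrays with the design and spread of the SPF comparison, with 50 genes changed at each size, the test recovered 20%, 66%, 94% and 98% of genes changed by a log2 of 0.5, 1, 2 and 3. Among the genes left unchanged on the same simulated arrays, the 5 comparisons gave 6, 0, 0, 7 and 3 false calls. In a simulated test of 41 lists of random genes, the 1 shifted list was found and 0 others were called. The simulated genes varied independently of each other, so that this does not test the preset correlation on lists whose genes vary together.

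Alternatives covered no background correction, the authors' log2 values, normalization without the BL6 arrays, median scaling, no filter and a stricter filter on dim probes (detection p under 0.01 on at least 10 arrays), all probes, array quality weights, a trended robust prior and a fit of only the 2 groups compared. They also covered the BL6 arrays with strain as a covariate, the BL6-labelled array without BL6 in its title counted as mixed, a test of a minimum fold change of 1.2, and each array left out in turn. Alternatives chosen after seeing the data were sex as a covariate (from Xist and Y-linked transcripts), leaving out 4 arrays that stood apart in the principal components (WT SPF replicates 1 and 2, gp130F/F SPF replicates 4 and 5), and the mean of the corpus and pancreas markers of each array as a covariate, which within groups follows the pancreas markers. A block for the array slide was not run, as the files used here give no slide. Far samples within a group were found with Dixon's ratio at the 95% critical value, and intervals over genes or arrays come from 10000 bootstrap resamples at 95%.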

Results

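The antrum is the lower part of the stomach, rich in mucous glands and in gastrin cells. Mice called gp130F/F are homozygous for an altered gp130, the receptor chain shared by cytokines of the interleukin-6 family and encoded by Il6st. A point mutation in it removes the docking site of the inhibitor SOCS3, and the mice are known to develop tumours of the antrum. The mixed-strain groups hold 5 wild-type SPF, 5 gp130F/F SPF, 4 wild-type germ-free and 5 gp130F/F germ-free samples, and the BL6 groups hold 1, 1, 2 and 1 in the same order. Mean signal per array ran from 398.8 (gp130F/F SPF replicate 5) to 665.1 (wild-type germ-free replicate 1), and 15705 to 19224 probes per array were detected. The highest correlation between any pair of arrays was 0.9864. The number of arrays limits the precision. By Xist and Y-linked transcripts, 1 of 5 wild-type SPF, 1 of 5 gp130F/F SPF, 2 of 4 wild-type germ-free and 2 of 5 gp130F/F germ-free samples were female. The first 4 principal components of the arrays held 21.8%, 15.2%, 9.02% and 7.95% of the variance.

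The first comparison asks how the antrum of gp130F/F mice differs from that of wild-type mice under SPF housing. Genes of acid-secreting and hormone-secreting cells were lower in gp130F/F mice (n = 5 and 5). Atp4b and Atp4a, the subunits of the parietal cell proton pump, fell by 8.11 ± 1.32 (log2, SE, adjusted p = 0.00062) and by 6.33 ± 1.06 (adjusted p = 0.00075). Both were detected on 1 of 5 gp130F/F arrays, so that the size of these falls depends on the background. Gast, the gastrin gene of antral G cells, fell from 15.31 ± 0.24 to 12.70 ± 1.59 (log2 level, SD, adjusted p = 0.005), and Sst, the somatostatin gene of D cells, fell by 3.11 ± 0.49 (adjusted p = 0.00049). The surface mucin gene Muc5ac changed by -0.85 ± 0.17 (adjusted p = 0.003), and Tlr2, a receptor for bacterial lipoproteins, by -1.96 ± 0.27 (adjusted p = 0.00013). The largest rise was that of Adh7, an alcohol dehydrogenase of the upper gut epithelium, which was detected in 5 of 5 gp130F/F samples and in 0 of 5 wild-type samples and was at least 47.6-fold higher (adjusted p = 2.2e-09).

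Further large rises in SPF mice were those of Me1, the cytosolic malic enzyme (at least 40.5-fold), Oit1 (at least 35.7-fold), Ctsc, the protease cathepsin C (log2 5.47 ± 0.22), H2-Bl (4.97 ± 0.70), A2ml1 (3.96 ± 0.99), Nccrp1 (3.27 ± 0.60), Acox2 (3.19 ± 0.35), Lrba (3.12 ± 0.15) and Gramd4 (at least 4.84-fold). Among wild-type arrays Ctsc was detected on 1 of 5 and H2-Bl on 3 of 5. The adjusted p-values ran from 1.5e-12 for Me1 to 0.012 for A2ml1. For each of the 10 genes all gp130F/F samples lay above all wild-type samples, which their choice as the largest rises favours (1 of the 126 splits of 10 arrays separates a gene not so chosen). The other large falls took in genes of pancreatic acinar cells and of gastric glands. How much pancreas tissue each dissected piece held was not measured, so that differences of acinar genes, here and in the other comparisons, need not be changes of the antrum. Pla2g1b, the pancreatic phospholipase, fell by 6.74 ± 1.02 (adjusted p = 0.00034), Pdia2 fell by 5.37 ± 0.89, Pnliprp1 fell by 4.81 ± 1.55 (adjusted p = 0.044), Rnase1 fell by 4.63 ± 1.45 (adjusted p = 0.037), Chia1, the acidic chitinase, fell by 4.55 ± 1.32 and Hamp2 fell by 4.37 ± 0.92. Sycn was at least 18.5-fold lower. On gp130F/F arrays Chia1 and Hamp2 were detected on 1 of 5, Pdia2 and Rnase1 on 2 of 5, and Pla2g1b and Pnliprp1 on 4 of 5, so that their sizes depend on the background (Chia1 was detected on 4 of 5 wild-type arrays). The groups did not overlap for 6 of these 10 genes, and did for Pnliprp1, Rnase1, Chia1 and Hamp2. Cptp, a ceramide-1-phosphate carrier, was at least 8.02-fold lower (5e-14), while its second probe gave 0.35. The other 8 fixed genes did not pass the test. Their log2 differences were 0.13 for Gkn1, 0.05 for Gkn2, -0.05 for Il6st, 0.24 for Stat3, 0.61 ± 0.30 for Socs3 (adjusted p = 0.18), 2.41 ± 1.40 for Reg3b (0.27) and 1.56 ± 1.09 for Reg3g (0.36, detected on 3 of 5 wild-type arrays), and Il11 was detected on none of the 10 arrays.

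Connective tissue and vessel genes were lower in gp130F/F SPF mice. Of 35 measured genes of fibroblasts and matrix, 29 fell and 0 rose (31 fell and 0 rose adjusted over the list alone), with Col1a2 at -2.89 ± 0.19 (adjusted p = 1.1e-08, detected on 1 of 5 gp130F/F arrays), Mfap5 at -2.45 ± 0.34 (0.00015), Col3a1 at -1.45 ± 0.21 (0.00024) and Col15a1 at -1.35 ± 0.15 (1.7e-05). The list had a median of -1.17 (camera, adjusted p = 1.9e-19, and adjusted p = 0.22 with an estimated correlation). Of 28 endothelial genes, 20 fell and 0 rose (22 and 0 adjusted over the list alone), among them Ccl21a (-2.52 ± 0.45, detected on 4 of 5 gp130F/F arrays), Mmrn1 (-1.54, detected on 3 of 5 gp130F/F arrays), Pecam1 (-1.07; its other probes gave -0.62 and 0.11) and Esam (-0.74). This list had a median of -0.886 (adjusted p = 9.3e-10, and adjusted p = 0.22 with an estimated correlation). Of 24 genes of endocrine cells, 18 fell and 0 rose (19 and 1 adjusted over the list alone). They included Ghrl, the ghrelin gene (-3.69 ± 0.63, adjusted p = 0.00087), Insm1, a transcription factor of endocrine cells (-2.18 ± 0.30, detected on 1 of 5 gp130F/F arrays), and Syp (-1.39 ± 0.21), and the median was -1.37 (adjusted p = 1.1e-10, and adjusted p = 0.22 with an estimated correlation). Genes of enteric neurons and glia had a median of -0.789, with 10 of 19 lower (10 adjusted over the list alone, adjusted p = 2.2e-06, and adjusted p = 0.22 with an estimated correlation). That median was -0.519 without gp130F/F SPF replicate 5 and -0.465 without the 4 arrays that stood apart (wild-type SPF replicates 1 and 2, gp130F/F SPF replicates 4 and 5). Of 28 genes of smooth muscle, 9 fell and 1 rose (15 and 1 adjusted over the list alone). The smooth muscle list had a median of -0.407 with adjusted p = 3.3e-05, and adjusted p = 0.62 with an estimated correlation (-0.727 with the corpus and pancreas markers as a covariate).

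Markers of other stomach regions and of the pancreas differed between the same SPF groups. Of 21 parietal and chief cell genes, 12 fell and 0 rose (14 and 0 adjusted over the list alone), including Kcne2, a subunit of the potassium channel of parietal cells (-3.03 ± 0.58, detected on 1 of 5 gp130F/F arrays), and Esrrg (at least 8.6-fold lower). The parietal and chief cell list had a median of -1.55 with adjusted p = 4.9e-06, and adjusted p = 0.22 with an estimated correlation. That median was -0.981 without the 4 arrays, and -1.52 with the corpus and pancreas markers as a covariate (adjusted p = 2.5e-05), a score that within groups followed the pancreas list (r = 0.959) and not the parietal and chief cell list (r = -0.0673). Of 22 pancreas genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone), with Clps at -3.09 ± 0.59 and Cela1 at -1.47 ± 0.39. The pancreas list had a median of -2.66 with adjusted p = 0.00018, and adjusted p = 0.66 with an estimated correlation. The median was -4.49 without the 4 arrays, -1.26 without wild-type SPF replicate 5, and turned to 2.38 with the corpus and pancreas markers, its own members among them, as a covariate. Of 25 genes of squamous epithelium, which lines the forestomach, 3 rose and 0 fell (2 and 0 adjusted over the list alone). The squamous list had a median of 1.10 with adjusted p = 0.0029, and adjusted p = 0.66 with an estimated correlation. Its call was lost without gp130F/F SPF replicate 4 (median 0.103, adjusted p = 0.29) and with the corpus and pancreas covariate (0.292, adjusted p = 0.26). The 3 that rose were Anxa8 (at least 4.27-fold), Ivl, the involucrin gene (2.97 ± 0.83, detected on 1 of 5 wild-type and 4 of 5 gp130F/F arrays), and Sprr2a1 (0.74 ± 0.25). The call of Sprr2a1 was lost in 16 of the 19 fits without 1 array (adjusted p up to 0.14). The plot of single samples shows the spread of these markers within groups.

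**Figure D1:**
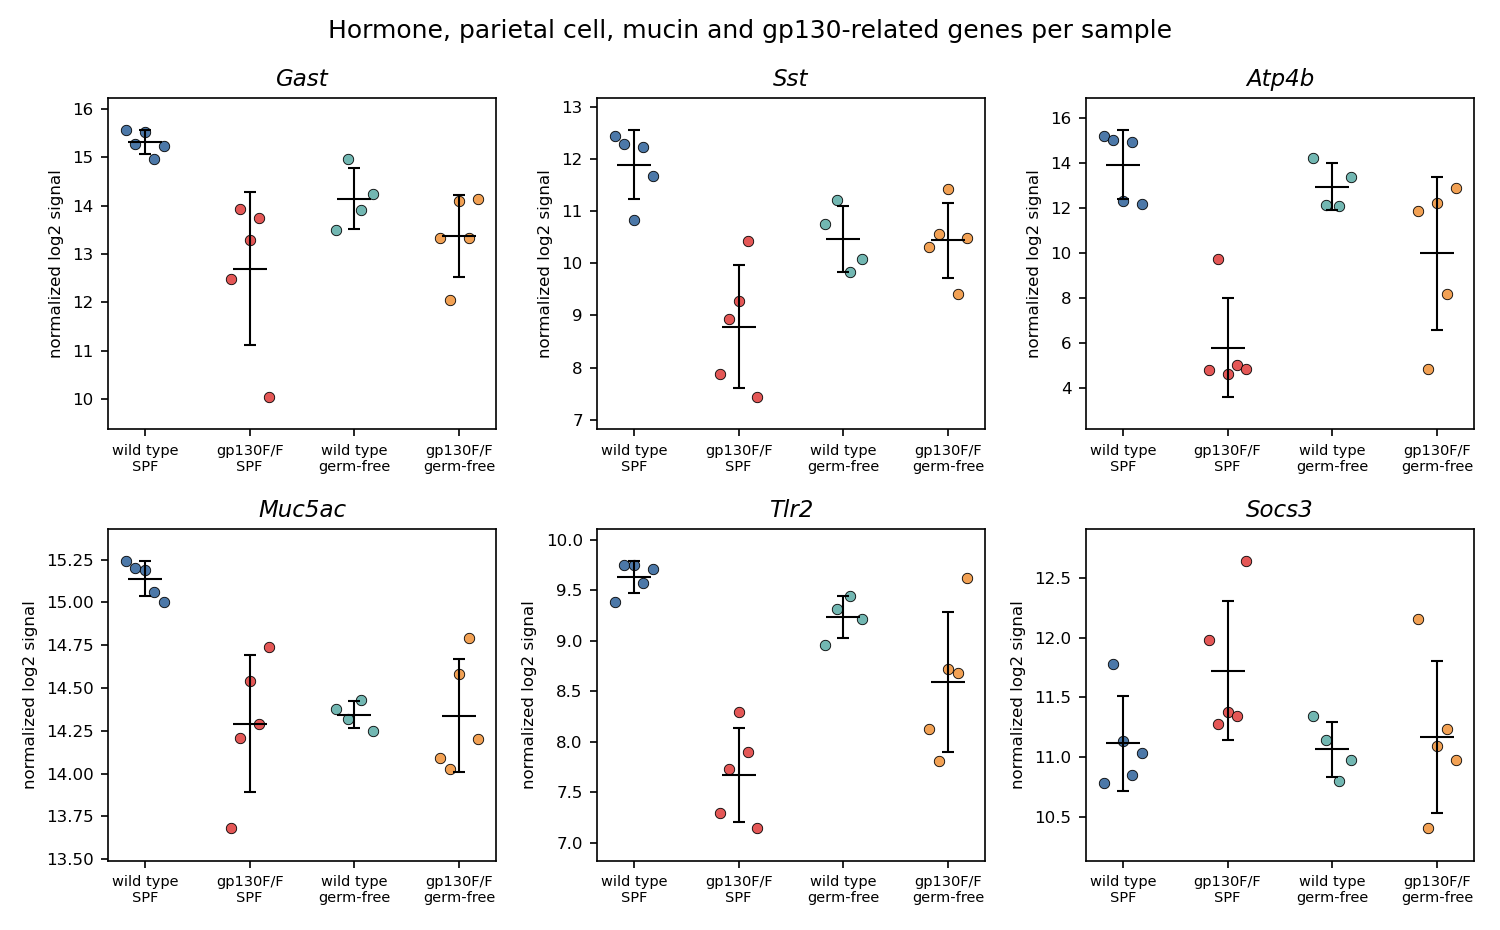
Normalized log2 signal of Gast, Sst, Atp4b, Muc5ac, Tlr2 and Socs3 in each mixed-strain sample of the 4 groups (points), with the group mean and SD (bars). Atp4b lay between 12.18 and 15.18 in wild-type SPF samples and between 4.86 and 12.87 in gp130F/F germ-free samples, of which 4 of 5 detected it.

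Mast cell and macrophage genes were also lower in gp130F/F SPF mice. Of 12 mast cell genes, 7 fell and 0 rose (8 and 0 adjusted over the list alone). The mast cell list had a median of -1.06 with adjusted p = 1e-05, and adjusted p = 0.22 with an estimated correlation. Those that fell included Tpsab1, a tryptase (-1.91 ± 0.33), Cma2, a chymase (-1.54 ± 0.24), Kit, the stem cell factor receptor (-1.30 ± 0.18), and Mcpt4 (at least 1.58-fold lower). Of 29 macrophage and dendritic cell genes, 11 fell and 0 rose (11 and 0 adjusted over the list alone), with Lyz2, a lysozyme, at -2.33 ± 0.46, the complement genes C1qb and C1qa at -1.83 ± 0.37 and -1.50 ± 0.31, and Adgre1, which encodes F4/80, at -1.38 ± 0.28. On gp130F/F arrays Tpsab1, Cma2 and C1qa were detected on 3 of 5, and Lyz2, C1qb and Adgre1 on 4 of 5. The macrophage and dendritic cell list had a median of -0.469 with adjusted p = 7e-05, and adjusted p = 0.26 with an estimated correlation (-0.747 without background correction). In the other direction, 9 of 27 genes for mucin glycosylation rose and 1 fell (9 and 2 adjusted over the list alone), among them St3gal4 (2.79 ± 0.41), Gcnt1 (1.60 ± 0.32), B3gnt3 (1.50 ± 0.14) and Galnt6 (1.03 ± 0.21), with St3gal4 and Galnt6 detected on 2 of 5 wild-type arrays. The glycosylation list had a median of 0.166 with adjusted p = 0.0015, and adjusted p = 0.22 with an estimated correlation (0.341 with the corpus and pancreas covariate). Of 31 targets of STAT3, the transcription factor downstream of gp130, 3 rose and 1 fell (4 and 1 adjusted over the list alone). Lrg1 rose by 2.79 ± 0.71 (adjusted p = 0.013), Il1rn by 1.36 ± 0.35 (0.013) and Junb by 0.72 ± 0.20 (0.021), Tlr2 was the one that fell, and the list did not pass the test (median 0.325, adjusted p = 0.06).

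In all, limma called 2290 of 15067 genes in the SPF comparison, 833 higher and 1457 lower, 588 of them by over 2-fold, and camera called 17 of 41 lists, 0 of them with an estimated correlation. The count was 1075, with 937 of the 2290 kept, without the 4 arrays that stood apart, and 1188, with 978 kept, with the corpus and pancreas markers as a covariate. In that last fit Pnliprp1 and Rnase1 turned to 0.78 and 0.89 and did not pass the test.

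The same genotype comparison in germ-free mice asks which differences were present without microbes (n = 5 gp130F/F and 4 wild type). Of the 10 largest falls, 6 were of mast cell genes. Mcpt1, a protease of mucosal mast cells, fell by 4.43 ± 0.28 (log2, SE, adjusted p = 6.5e-09, detected on 3 of 5 gp130F/F arrays), Cma2 fell by 3.66 ± 0.26 (3.8e-08), Tpsab1 fell by 3.46 ± 0.35 (5.2e-06) and Cpa3, the mast cell carboxypeptidase, fell by 3.00 ± 0.34 (2.5e-05). Mcpt4 was at least 7.97-fold lower, and Fcer1a, the alpha chain of the high-affinity IgE receptor, at least 5.98-fold lower. Of 12 mast cell genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone). The mast cell list had a median of -2.92 with adjusted p = 2.1e-30, and adjusted p = 0.0021 with an estimated correlation. The largest rises were again those of Adh7 (at least 60.3-fold, adjusted p = 1.8e-09), Ctsc (6.04 ± 0.23, 6.7e-12), Me1 (at least 30-fold) and Oit1 (at least 24.3-fold).

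Among the other large changes in germ-free mice, Plk1, a kinase of mitosis, was at least 9.59-fold higher in gp130F/F mice and Ccng2, a cyclin G gene, at least 9.88-fold lower. H2-Bl rose by 4.39 ± 0.75, Acox2 by 3.02 ± 0.37, Lrba by 2.72 ± 0.16, Xlr4a by 2.71 ± 0.55 and Anxa8 by at least 3.89-fold. Of 4 wild-type arrays, Ctsc and H2-Bl were detected on 1, Acox2 on 2 and Xlr4a on 3. Cptp was at least 8.96-fold lower (its second probe gave 0.61) and Epm2aip1 at least 8.62-fold lower (its other 4 probes gave -0.61 to 0.52), and Pla2g4c fell by 3.51 ± 0.71. For all 20 genes the samples of the 2 groups did not overlap, which their choice by size favours (2 of the 126 splits of 9 arrays separate a gene not so chosen). None of the 11 measured fixed genes passed the test, with log2 differences of -0.77 to 3.58 and a smallest adjusted p of 0.32. Of 45 genes of xenobiotic metabolism, Adh7 rose and 0 fell (1 and 0 adjusted over the list alone), and the list had a median of 0.121 (adjusted p = 0.0097, and adjusted p = 0.87 with an estimated correlation), which was 0.202 without gp130F/F germ-free replicate 1 and 0.0768 without replicate 3, where the call was lost (adjusted p = 0.13). Cbr1 (0.50), Cyp2c65 (0.43) and Sod1 (0.31) did not pass the test. Parietal and chief cell genes had a median of -0.534 (adjusted p = 0.011, and adjusted p = 0.87 with an estimated correlation) and pancreas genes one of 1.59 (adjusted p = 0.0097, and adjusted p = 0.88 with an estimated correlation), with 0 members of either past the test (0 adjusted over the list alone). Endothelial genes had a median of 0.231 and 0 members past the test (0 adjusted over the list alone, adjusted p = 0.0097, and adjusted p = 0.88 with an estimated correlation). Without gp130F/F germ-free replicate 2 the calls of the parietal, pancreas and endothelial lists were lost, with medians of -0.398, 0.552 and 0.134 (adjusted p = 0.072, 0.46 and 0.092). The parietal call was also lost without wild-type germ-free replicate 1 (-0.341, adjusted p = 0.098) and the endothelial call without replicate 3 (0.163, adjusted p = 0.09), and the pancreas median was 0.705 with the corpus and pancreas covariate.

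For germ-free mice limma called 314 genes, 151 higher and 163 lower, and camera called 7 of 41 lists, 1 of them (mast cells) with an estimated correlation. The fit with array quality weights gave 591 genes and the test of a minimum fold change of 1.2 gave 141. The SPF and germ-free comparisons use separate arrays, and 104 genes were higher in both (8.35 expected if the calls were independent), 85 were lower in both (15.8 expected) and 5 went in opposite directions. Both comparisons used 1 shared estimate of the spread per gene, so that a gene with a low estimate tends to be called in both. The expected numbers are therefore too low as a reference. This sharing does not favour the same direction over the opposite one. Across all 15067 genes, which are not independent replicates, the log2 differences of the 2 comparisons had a Pearson r of 0.29 and a Spearman rho of 0.12.

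**Figure D2:**
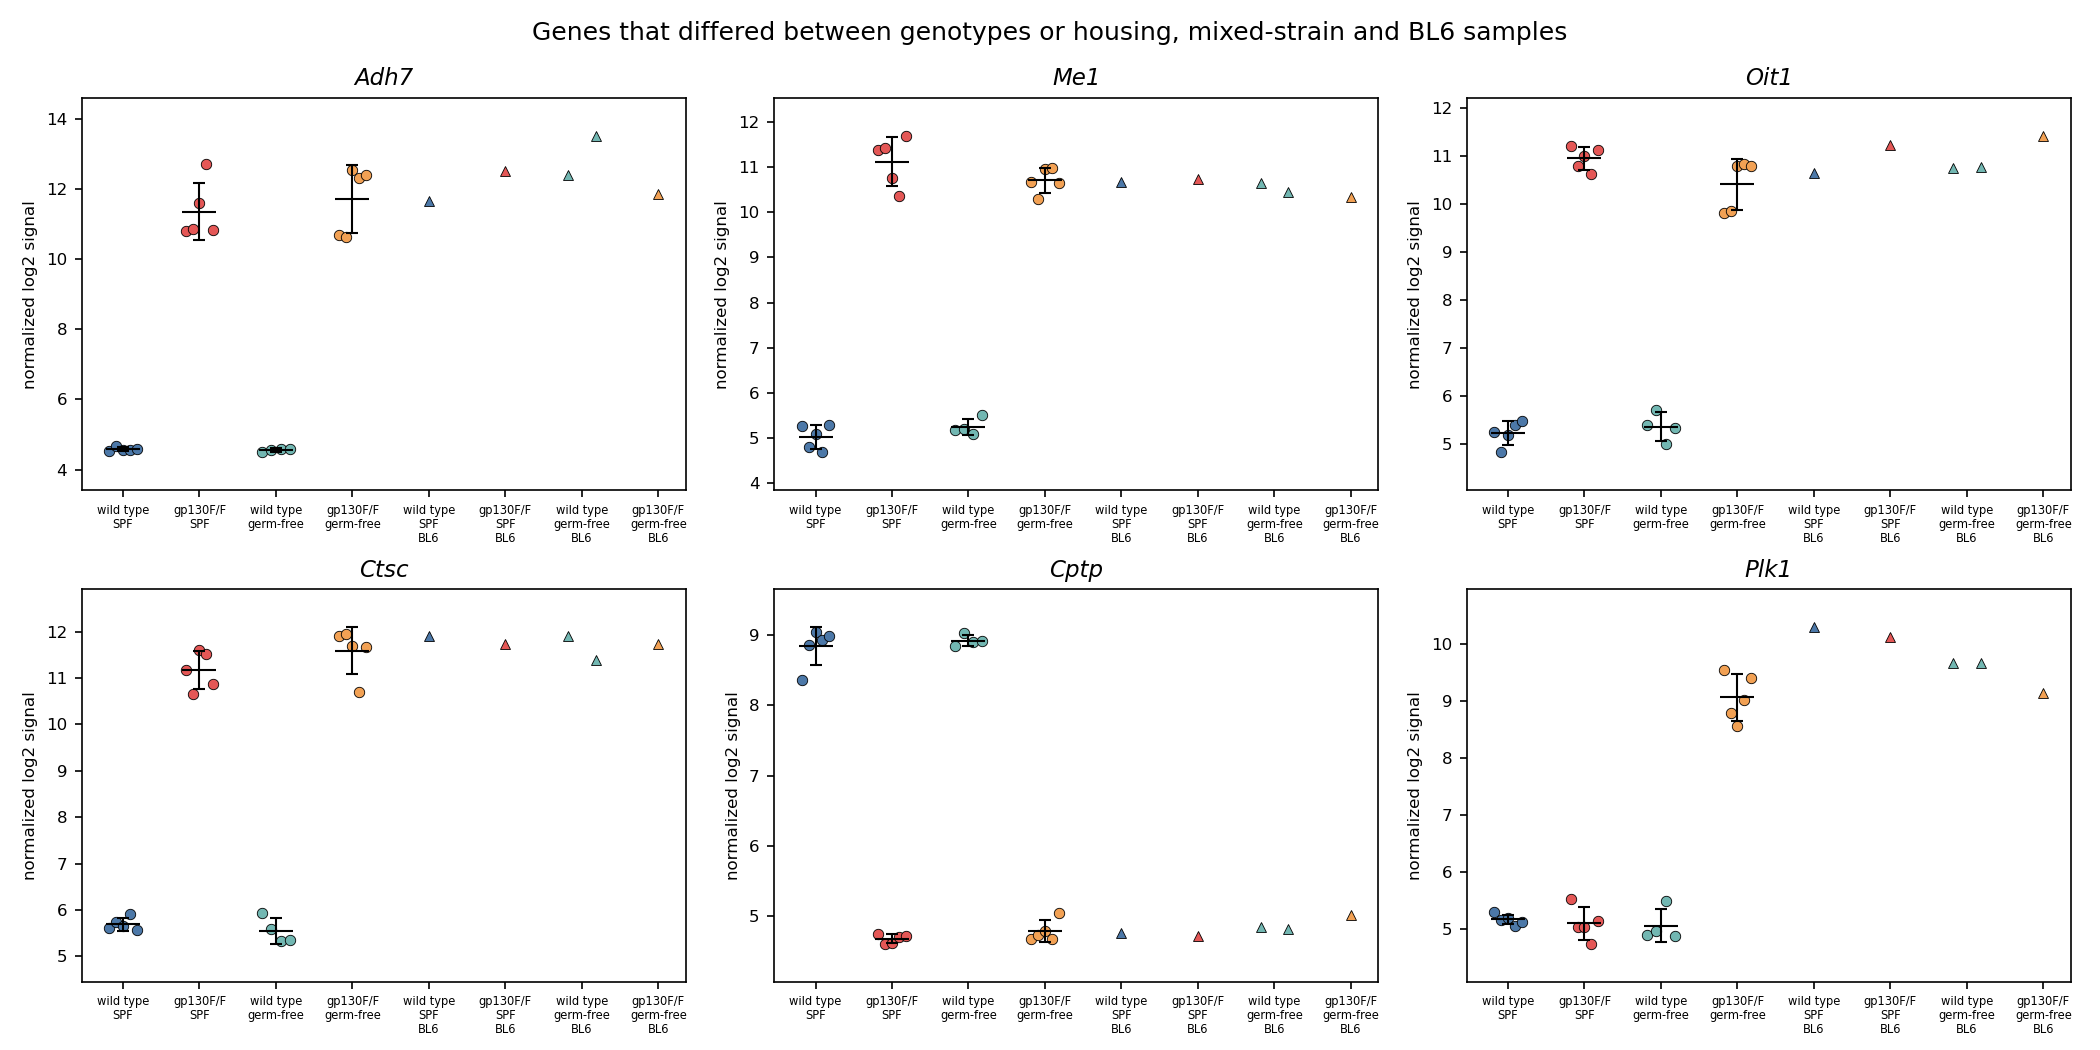
Normalized log2 signal of Adh7, Me1, Oit1, Ctsc, Cptp and Plk1 in each sample of the 8 groups, with circles and the mean and SD (bars) for mixed-strain samples and triangles for BL6 samples. Adh7 had a mean of 4.58 in mixed-strain and a value of 11.66 in BL6 wild-type SPF mice.

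Samples of the BL6 strain enter no comparison, and their levels are given beside the shared genotype differences as background. In BL6 wild-type mice Adh7 stood at 11.66 under SPF housing (n = 1) and at a mean of 12.96 in germ-free housing (n = 2), against 11.36 ± 0.82 in mixed-strain gp130F/F SPF mice (SD, n = 5) and 4.58 ± 0.06 in mixed-strain wild-type SPF mice (n = 5). Cptp stood at 4.75 in BL6 wild-type SPF mice, at 4.67 ± 0.06 in mixed-strain gp130F/F and at 8.84 ± 0.27 in mixed-strain wild-type SPF mice. Me1 (10.68), Oit1 (10.64), Ctsc (11.90) and Gramd4 (8.31) were likewise near the mixed-strain gp130F/F levels in the BL6 wild-type SPF sample. Over the 189 genes called in the same direction in both housing conditions, 104 (55%) had all 3 BL6 wild-type arrays beyond all 9 mixed-strain wild-type arrays on the side of the gp130F/F mice and 2 on the opposite side, against 423 of the 14878 other genes (2.84%). Col1a2 was different, with 9.02 and 8.34 in the BL6 wild-type and gp130F/F SPF samples and 5.73 ± 0.24 in mixed-strain gp130F/F SPF mice. The 189 genes were chosen by the same 9 mixed-strain wild-type arrays, which favours finding other arrays beyond these. The 14878 other genes were not so chosen.

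The size of the genotype effect under the 2 housing conditions was compared on genes called for their average effect. The choice and the test used the same arrays. The lowest array quality weights, which mark noisier arrays, were 0.3 and 0.483, for gp130F/F SPF replicates 5 and 4. They were 0.737 to 1.85 in the germ-free groups. Such unequal spread can favour larger SPF effects among the chosen genes, and array weights were not run for this result. For 872 genes that fell on average, the median effect was -0.737 in SPF mice and -0.339 in germ-free mice, and 668 of them (76.6%) had a smaller effect in germ-free mice. The median difference was 0.315 (camera p = 3.4e-15; p = 0.015 with an estimated correlation). For 527 genes that rose on average the medians were 0.645 and 0.475, 356 (67.6%) had a smaller effect in germ-free mice, and the median difference was -0.186 (camera p = 2.3e-05; p = 0.041 with an estimated correlation).

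Germ-free and SPF wild-type mice were compared to show what differed between the housing conditions in mice with normal gp130 (n = 4 and 5). Their germ-free samples are also those of the preceding germ-free genotype comparison. Mast cell genes were higher in germ-free mice. Mcpt1 rose from 6.32 ± 0.57 to 10.27 ± 0.46 (log2 level, SD, adjusted p = 3.3e-07), Tpsab1 rose by 4.04 ± 0.35 (log2, SE; 4.8e-06), Fcer1a by 2.71 ± 0.19 (3.3e-07), Cpa3 by 2.63 ± 0.34 (0.00065), Tpsb2 by 2.54 ± 0.31 (0.00035) and Cma1 by 2.41 ± 0.23 (1.7e-05). In SPF mice Fcer1a was detected on 1 of 5, Cma1 on 3 of 5 and Tpsb2 on 4 of 5 arrays. Of 12 mast cell genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone). The mast cell list had a median of 2.46 with adjusted p = 2.6e-23, and adjusted p = 0.0078 with an estimated correlation. The largest rises were those of the chitinase-like genes Chil4 (7.22 ± 1.33, adjusted p = 0.011) and Chil3 (6.34 ± 0.91, 0.0018), but neither size is exact. Chil3 was detected on 1 of 5 SPF arrays, with a mean of 5.43 near the background, and the germ-free mean of Chil4, 15.95, lay near the highest normalized value of any probe, 16.02.

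Other rises in germ-free wild-type mice were those of Pla2g4c (4.02 ± 0.71), Gsdmc2, a gasdermin (3.18 ± 0.74), and Rnase2a, a ribonuclease of the eosinophil family (at least 3.42-fold). Fibroblast and matrix genes were lower. Of 35, 8 fell and 0 rose (20 and 0 adjusted over the list alone), with Mfap5 at -1.51 ± 0.36, Fbln2 at -1.42 ± 0.25, Col3a1 at -1.40 ± 0.22, Col1a2 at -1.05 ± 0.20 and Loxl1 at -0.98 ± 0.20. The fibroblast and matrix list had a median of -0.693 with adjusted p = 8.9e-13, and adjusted p = 0.58 with an estimated correlation. Cd248, a surface protein of stromal cells, fell by 1.73 ± 0.30 and Hic1 was at least 2.48-fold lower. Clca4a (-2.27, with 0.12 for its second probe), Ly6g6c (-2.11), B3galt5 (-1.59), Gfpt2 (-1.58) and Ppfia3 (-1.54), each detected on 3 of 4 germ-free arrays, Tppp3 (-1.49) and Slurp1 (-1.45) made up the rest of the 10 largest falls, and the groups did not overlap for any of the 20 genes, chosen by size (2 of 126 splits for a gene not so chosen). Smooth muscle genes had a median of -0.535, with 1 lower (7 adjusted over the list alone, adjusted p = 2.8e-09, and adjusted p = 0.58 with an estimated correlation). Of 27 genes for mucin glycosylation, 3 rose and 0 fell (6 and 0 adjusted over the list alone), namely St3gal4 (1.96 ± 0.44, detected on 2 of 5 SPF arrays), St3gal6 (1.10 ± 0.19) and Fut4 (0.76 ± 0.19), and St6galnac2 had 0.53 and did not pass. The call of Fut4 was lost in most, and that of St3gal4 in some, of the fits without 1 array. The glycosylation list had a median of 0.347 with adjusted p = 2.7e-05, and adjusted p = 0.27 with an estimated correlation (0.2 without the 4 arrays that stood apart). Muc5ac changed by -0.79 ± 0.18 (adjusted p = 0.032), and the other 10 fixed genes did not pass, with -1.82 to 0.37 and a smallest adjusted p of 0.28. Pancreas genes had a median of -2.69 with 0 members past the test (0 adjusted over the list alone, adjusted p = 2.7e-05, and adjusted p = 0.68 with an estimated correlation). It was -4.44 without the 4 arrays and -1.42 without wild-type SPF replicate 5, and turned to 0.16 with the corpus and pancreas covariate, where the call was lost (adjusted p = 0.22).

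**Figure D3:**
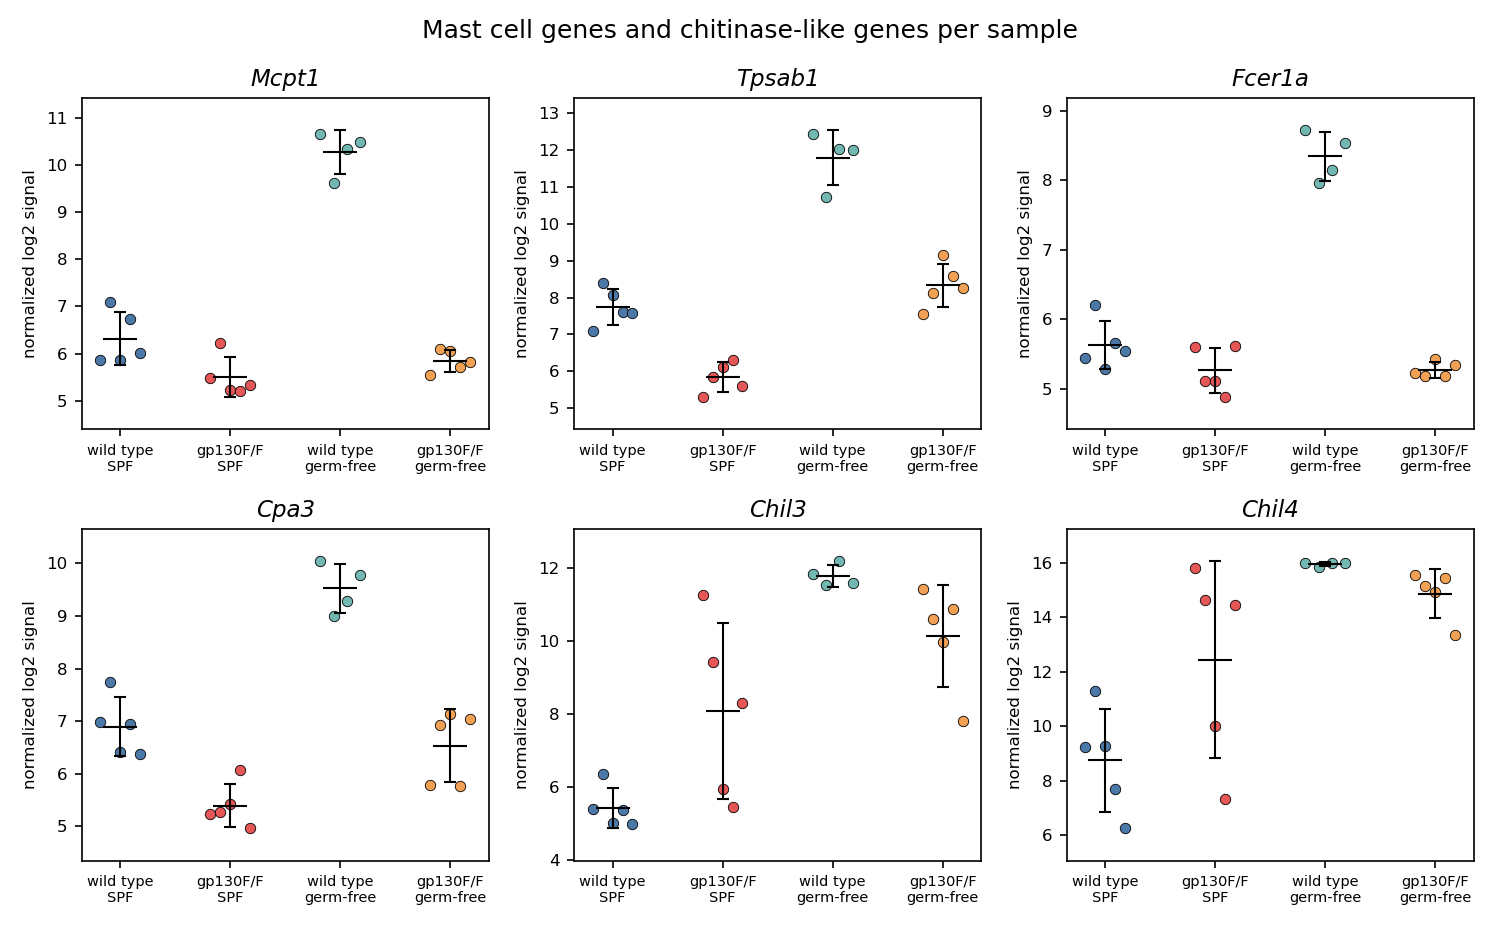
Normalized log2 signal of Mcpt1, Tpsab1, Fcer1a, Cpa3, Chil3 and Chil4 in each mixed-strain sample of the 4 groups (points), with the group mean and SD (bars). The 4 wild-type germ-free samples have Mcpt1 levels of 9.61 to 10.66, and the 5 gp130F/F germ-free samples 5.54 to 6.10, of which 3 of 5 detected it.

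For wild-type mice limma called 286 genes between the housing conditions, 148 higher and 138 lower, and camera called 11 lists, 1 of them (mast cells) with an estimated correlation. The count ran from 72 without wild-type germ-free replicate 3 to 466 without gp130F/F SPF replicate 5. The share of calls that were higher was 51.7%, and 77.6% with median scaling.

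The matching comparison in gp130F/F mice asks what differed between the housing conditions in mutant mice (n = 5 and 5). The genotype, housing and strain labels give no colony, so that housing cannot be told apart from colony in either genotype. Lists of vessel, connective tissue and clock genes were called with the preset correlation and not with the estimated one. Of 28 endothelial genes, 5 rose and 0 fell (20 and 1 adjusted over the list alone), with Pecam1 at 1.17 (adjusted p = 0.024; its other probes gave 0.85 and -0.01), Egfl7 at 0.70 ± 0.13 (0.017), Esam at 0.67 (0.031) and Robo4 at 0.70 (0.023; its other probes gave -0.39 and -0.55). The endothelial list had a median of 0.725 with adjusted p = 4.6e-13, and adjusted p = 0.31 with an estimated correlation. Of 35 fibroblast and matrix genes, Col15a1 rose by 0.85 ± 0.15 (adjusted p = 0.012) and 0 fell (24 rose and 0 fell adjusted over the list alone), and Mfap5 (1.40), Mfap4 (1.00) and Fbln1 (0.57) did not pass. The fibroblast and matrix list had a median of 0.62 with adjusted p = 1.7e-13, and adjusted p = 0.46 with an estimated correlation. Among 16 genes of the circadian clock, 6 fell and 1 rose (8 and 1 adjusted over the list alone). The circadian list had a median of -0.576 with adjusted p = 0.0003, and adjusted p = 0.11 with an estimated correlation. Ciart fell by 2.25 ± 0.30, Dbp fell by 1.97 ± 0.43, Tef fell by 1.60 ± 0.30 and Per2 fell by 1.53 ± 0.27, while Arntl, which encodes the clock activator BMAL1, rose by 1.82 ± 0.28. Ciart was detected on 2 of 5 germ-free and Arntl on 4 of 5 SPF arrays. The genotype, housing and strain labels give no time of day of collection, so that for clock genes it cannot be told apart from housing.

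The largest rises in germ-free gp130F/F mice were those of Pdia2 (4.26 ± 0.89), Plk1 (at least 9.33-fold), Mptx1 (3.52 ± 0.72), Lpl, the lipoprotein lipase (2.72 ± 0.49), Tpsab1 (2.49 ± 0.33), Plac9a (2.18 ± 0.23), Cfap69 (2.10 ± 0.42), Ccl27a (2.07 ± 0.19), Fam183b (1.94 ± 0.24) and Retnla (1.83 ± 0.40). Of these, Mptx1, Plac9a and Retnla were detected on 1 of 5, Pdia2 on 2 of 5, Tpsab1 on 3 of 5 and Cfap69 on 4 of 5 SPF arrays, so that their sizes depend on the background. Ccng2 was at least 5.94-fold lower, and the squamous gene Sprr1a (-1.46), Slurp1 (-1.25), Cfap45 (-1.23), Bach1 (-1.18) and Frmpd1 (-1.06, detected on 1 of 5 germ-free arrays) fell too. Apart from Cfap69, none of these 20 genes, the clock genes included, had groups that overlapped, as their choice by size favours (1 of 126 splits for a gene not so chosen). Of 45 interferon response genes, 0 passed (9 fell and 0 rose adjusted over the list alone). The interferon list had a median of -0.368 with adjusted p = 3.8e-07, and adjusted p = 0.46 with an estimated correlation (-0.22 without gp130F/F SPF replicate 3). The members with the smallest p were Oasl2 (-1.82), Dhx58 (-1.01), Oas1g (-0.92) and Irf9 (-0.68). Pancreas genes had a median of 1.65 with 0 members past the test (1 adjusted over the list alone, adjusted p = 0.00037, and adjusted p = 0.74 with an estimated correlation). Parietal and chief cell genes had one of 0.449 with 0 past the test (1 adjusted over the list alone, adjusted p = 0.029, and adjusted p = 0.74 with an estimated correlation). The pancreas call was lost without gp130F/F germ-free replicate 2 (median 0.705, adjusted p = 0.14), and its median turned to -1 with the corpus and pancreas covariate. The parietal call was lost without the 4 arrays that stood apart (0.483, adjusted p = 0.093), without gp130F/F SPF replicates 1 and 4 (adjusted p = 0.088 and 0.13) and without gp130F/F germ-free replicates 3 and 5 (adjusted p = 0.083 and 0.088). None of the 11 fixed genes passed, with -0.65 to 0.92 and a smallest adjusted p of 0.09.

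In gp130F/F mice limma called 169 genes, 100 higher and 69 lower, and camera called 14 lists, 0 of them with an estimated correlation. The count was 720 without gp130F/F SPF replicate 4, 61 without gp130F/F germ-free replicate 2, and 16 in a fit of only the 2 groups.

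**Figure D4:**
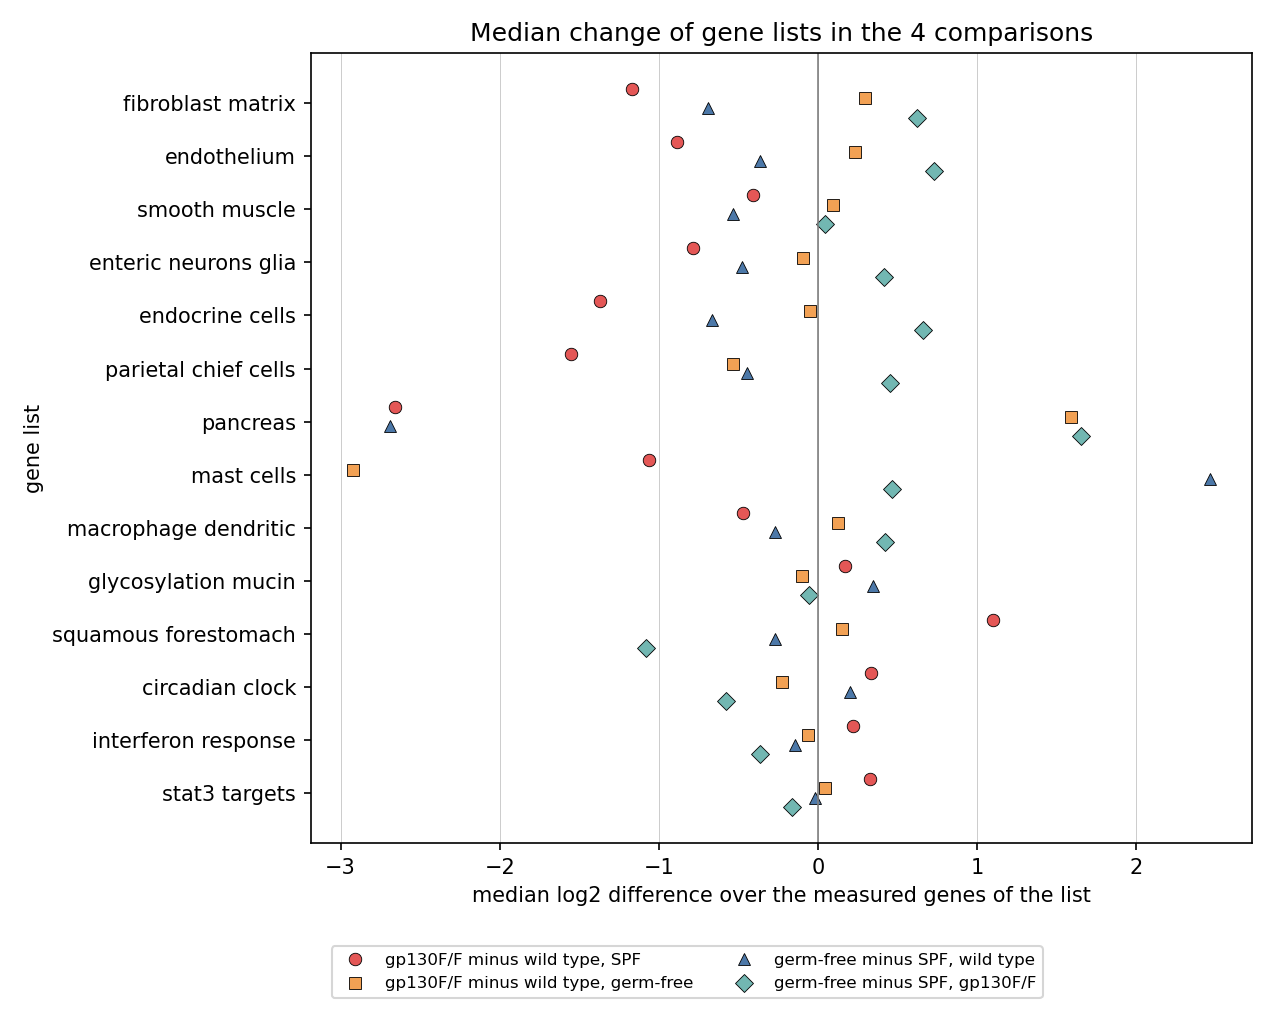
Median log2 difference (horizontal axis) of the measured genes of 14 gene lists (vertical axis), with 1 marker for each of the 4 comparisons between groups and no error bars. Mast cell genes had a median of 2.46 between germ-free and SPF wild-type mice and of -2.92 between gp130F/F and wild-type germ-free mice.

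The last comparison tests directly whether the genotype effect differed between housing conditions, as the difference of the germ-free and the SPF genotype effect (n = 5, 4, 5 and 5). The genotype effect on stromal genes was more positive in germ-free mice. Of 35 fibroblast and matrix genes, 15 had a higher genotype effect in germ-free mice and 0 a lower one (27 and 0 adjusted over the list alone), with Mfap5 at 2.91 ± 0.49 (log2, SE, adjusted p = 0.0081), Col14a1 at 2.58 (0.023), Fbln2 at 2.12 (0.0068), Col3a1 at 2.00 (0.0045) and Col15a1 at 1.27 (0.0097). The fibroblast and matrix list had a median of 1.27 with adjusted p = 5.4e-22, and adjusted p = 0.18 with an estimated correlation. A higher effect in germ-free mice also held for 5 of 28 endothelial genes (21 adjusted over the list alone), among them Tek, an angiopoietin receptor (2.15), Eng (1.88), Sox18 (1.56) and Esam (1.04). The calls of Eng and Sox18 were lost in 14 and 13 of the 19 fits without 1 array (adjusted p up to 0.1 and 0.089). The endothelial list had a median of 1.13 with adjusted p = 1e-13, and adjusted p = 0.18 with an estimated correlation. The same was true of 3 of 24 endocrine genes (16 adjusted over the list alone), with Sst at 3.07 ± 0.71, Insm1 at 2.09 and Nkx2-2 at 1.62, while Syp had 1.18 and did not pass (0.051). Those of Nkx2-2 and Sst were lost in 14 and 10 of these fits (adjusted p up to 0.088 for both). Col14a1 and Insm1 were detected on 1 of 5, Nkx2-2 on 2 of 5, Tek on 3 of 5 and Eng and Sox18 on 4 of 5 gp130F/F SPF arrays. The endocrine list had a median of 1.36 with adjusted p = 5.9e-10, and adjusted p = 0.22 with an estimated correlation. Mast cell genes went the other way, with 6 of 12 lower (9 lower and 1 higher adjusted over the list alone), as for Mcpt1 (-3.61 ± 0.38, adjusted p = 0.00011), Fcer1a (-2.70 ± 0.27, 5.6e-05), Mcpt4 (-2.26), Cma1 (-2.22) and Cma2 (-2.12). Of these, Fcer1a and Mcpt4 were detected on 0 of 5, Mcpt1 and Cma1 on 1 of 5 and Cma2 on 3 of 5 gp130F/F SPF arrays. These values therefore depend on the background, that of Cma2 included, and are no folds. The mast cell list had a median of -1.74 with adjusted p = 1.5e-09, and adjusted p = 0.17 with an estimated correlation.

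The difference was also above 0 for Pla2g1b (6.43 ± 1.49), Pdia2 (5.71 ± 1.30), Plk1 (4.07 ± 0.26), Lpl (3.60 ± 0.71), Lyz2 (3.11 ± 0.67; its other probes gave 2.09 and -0.15), Scara5 (3.09; -0.34 for its second probe) and Plac9a (2.78). Plk1 was undetected in 3 of the 4 groups, Plac9a in wild-type germ-free and Ccng2 in gp130F/F germ-free mice, so that their values are differences of fitted signals and no folds. It was below 0 for Ccng2 (-3.36), Slc7a11, a cystine carrier (-2.70), Ciart (-2.66), St3gal4 (-2.63) and Sftpd, surfactant protein D (-2.54). Pdia2 was detected on 2 of 5 gp130F/F SPF, Ciart on 2 of 5 gp130F/F germ-free and St3gal4 on 2 of 5 wild-type SPF arrays. Some of these calls were lost in fits without 1 array, most often those of Pla2g1b, St3gal4, Pdia2, Scara5 and Slc7a11. Pancreas genes had a median of 4.28 with 0 members past the test (4 adjusted over the list alone, adjusted p = 8.5e-08, and adjusted p = 0.54 with an estimated correlation). Parietal and chief cell genes had one of 1.03 with 0 past the test (1 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.71 with an estimated correlation). The parietal call was lost without the 4 arrays that stood apart (median 0.496, adjusted p = 0.32) and without gp130F/F SPF replicate 4 (0.989, adjusted p = 0.063), and the pancreas median turned to -1.45 with the corpus and pancreas covariate. None of the 11 fixed genes passed, with -0.50 to 1.85 and a smallest adjusted p of 0.081, so that the falls of Gast, Muc5ac and Tlr2 in SPF mice are not shown to differ from their germ-free values.

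For this difference limma called 293 genes, 193 above and 100 below 0, and camera called 13 lists, 0 of them with an estimated correlation. The count was 999 without gp130F/F SPF replicate 4, 80 without wild-type germ-free replicate 4, 29 with the BL6 arrays included and strain as a covariate, and 41 with the corpus and pancreas markers as a covariate.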

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

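Of the tests of explanations below, those other than the splits of the samples were chosen only after the result was seen, sex as a covariate included, though the bounds for the sex tests were set before those fits were run. The requirement that an interval clear a bound was added after the values were seen, for the ratios of the first pattern and for the dilution test, as were the division of the mast cell genes by detection and the corpus test on genes detected on all arrays.

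A first pattern was the set of 189 genes that differed in the same direction between gp130F/F and wild-type mice under both housing conditions, led by Adh7, Me1, Oit1, Ctsc and Cptp. The sex ratio was the same in both SPF groups (1 female of 5 in each), so that an unequal ratio could not give the SPF calls. With sex as a covariate 93.1% of the genes stayed called in both conditions, which adds little to this. The gp130F/F minus wild-type difference among BL6 arrays was a median of 0.000405 times that in mixed-strain mice (95% bootstrap interval over genes -0.0169 to 0.0418), which argues against the genotype itself as the cause for the set as a whole. The difference of the BL6 from the mixed-strain wild-type SPF samples was a median of 0.797 times the germ-free genotype effect (0.664 to 0.901), so that alleles of the background strain that differ between the mixed wild-type and gp130F/F lines are a candidate explanation. The same wild-type SPF samples had served to choose these genes, which favours this ratio. What stays open is each single gene (126 of the 189 had a ratio above 0.5), whether such alleles change the transcript or the binding of the probe, and the spread between BL6 animals, since the intervals cover genes and the BL6 groups hold 1, 1, 2 and 1 arrays.

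A second pattern was the fall of endocrine, parietal and chief cell genes in gp130F/F SPF mice. Less corpus tissue in the dissected piece would not lower Gast, which antral G cells make, and the log2 change of Gast of -2.61 argues against it as the whole cause of the endocrine fall. For the parietal and chief cell genes less corpus tissue cannot be told apart, since the 3 called genes detected on all 19 arrays ranged among gp130F/F germ-free samples over 0.473 (Cblif), 0.516 (Clic6) and 0.719 (Pga5) of the SPF difference, around the bound of 0.5, and since the covariate of corpus and pancreas markers, which left the list at -1.52, followed the pancreas within groups (r = 0.959) and not these genes (r = -0.0673). Dilution by a thicker surface epithelium would lower the other cells alike. The median of the endocrine list lay below that of smooth muscle (-0.96, with intervals of -1.25 to -0.54 over genes and -1.39 to -0.53 over arrays). With smooth muscle as the only reference, this argues against dilution as the whole cause of the endocrine fall. Fibroblast and matrix (-1.17), endothelial (-0.886) and enteric neuron and glia genes (-0.789) fell by more than smooth muscle (-0.407), nearer to the endocrine median (-1.37). Against these lists dilution was not tested. For the parietal and chief cell list (-1.14, -2.67 to 0.31 over genes and -1.89 to -0.23 over arrays) dilution cannot be told apart. Of the 21 parietal and chief cell genes 1 stands in another list, as do 1 of the 24 endocrine and 0 of the 22 pancreas genes, and an effect of the genotype on these cells was not tested apart from these.

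The last pattern was the rise of mast cell genes in germ-free wild-type mice. All 9 called genes stayed called with sex as a covariate, which argues against the unequal sex ratio. Germ-free housing alone, whatever the line, would raise these genes alike in gp130F/F mice. Cma2, Tpsab1 and Gata2 were detected on 3, 3 and 4 of 5 gp130F/F SPF arrays. Their median gp130F/F share of the unlogged wild-type signal was 0.286 in SPF and 0.0863 in germ-free mice, a ratio of 0.302 (95% interval over arrays 0.157 to 0.696). The genes were chosen by their rise between the same wild-type groups, which favours a low ratio, and the interval does not redo this choice. The ratio is therefore weak evidence against housing alone as the whole cause for these 3 as a set. The direct test passed for Cma2 alone (-2.12, against -1.55 with adjusted p = 0.091 for Tpsab1 and -1.08 with 0.083 for Gata2). For the other 6, detected on at most 1 of 5 gp130F/F SPF arrays, housing alone cannot be told apart, since the share in SPF mice is an upper limit near the background (ratio 0.32, 0.145 to 0.647). What stays open is a response to housing that depends on genotype or colony. Among BL6 wild-type arrays (1 SPF, 2 germ-free) the rise was a median of 0.249 times that in mixed-strain mice (0.0586 to 0.482 over genes). By its transcripts that SPF array was male and both germ-free arrays were female, so that sex and housing cannot be told apart there. The interval holds no spread between animals, and the choice of the genes by their rise in mixed-strain mice favours a low value here too. A type 2 immune response in the germ-free wild-type colony also stays open, since 7 of 20 measured genes (35%) of a type 2 list of 28 genes, written after the data were seen, rose, between the bounds set for either reading.

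Other splits of the samples, 100 of the 126 possible for each comparison of 2 groups and 100 of 31752 for the housing labels, were run for each count, with the real split included in the number given. In the SPF comparison 1 split gave as many genes (2290, highest other 403), in the germ-free comparison 1 (314, highest other 93) and in wild-type mice 1 (286, highest other 25). Chance can be excluded for these 3 at the level of 0.05, unadjusted. In gp130F/F mice 2 splits did (169, highest other 176). This count passes the unadjusted level of 0.05, but another split gave more genes, so that chance is not firmly excluded. For the difference between housing conditions 1 split gave as many (293, highest other 3), and for the median difference among genes that fell 1 gave as much (0.315, highest other 0.253). Exchanging housing labels within each genotype also turns any housing effect into spread within groups, which can lower the values of the splits. These splits therefore cannot show that chance is excluded for the difference itself.

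Among 572 sets of values of a gene or list in a group, 45 (7.87%) had 1 sample far from the rest, with a gap to the nearest sample above the 95% critical share of the group's range. Chance gives about 5% of sets. The share follows each gene in parentheses. Wild-type SPF replicate 1 was highest for Eng (0.766) and lowest for Cptp (0.733) and St3gal6 (0.848). Wild-type SPF replicate 2 was highest for B3gnt3 (0.862), Cma2 (0.904), Gsdmc2 (0.787) and Mcpt4 (0.935). Wild-type SPF replicate 3 was lowest for Clps (0.905) and Pdia2 (0.731). Wild-type SPF replicate 5 was highest for Col3a1 (0.74). Sample gp130F/F SPF replicate 1 was lowest for A2ml1 (0.8). Sample gp130F/F SPF replicate 2 was highest for Atp4a (0.922), Atp4b (0.92), Hamp2 (0.881), Mcpt1 (0.724), Pdia2 (0.734) and Pla2g1b (0.83). Sample gp130F/F SPF replicate 3 was lowest for Reg3g (0.758). Sample gp130F/F SPF replicate 4 was highest for Fbln2 (0.75), Mfap4 (0.78), Plac9a (0.756) and Xlr4a (0.826) and lowest for B3gnt3 (0.735) and Gkn1 (0.715). Sample gp130F/F SPF replicate 5 was highest for Frmpd1 (0.711) and lowest for Cfap69 (0.844) and Mptx1 (0.714). Wild-type germ-free replicate 1 was highest for Chia1 (0.845) and lowest for Dhx58 (0.925). Wild-type germ-free replicate 2 was highest for Adgre1 (0.847) and Scara5 (0.865) and lowest for Chil4 (0.867). Wild-type germ-free replicate 3 was highest for Galnt6 (0.881) and Plk1 (0.851) and lowest for C1qa (0.873) and Eng (0.908). Wild-type germ-free replicate 4 was lowest for Gkn2 (0.878). Sample gp130F/F germ-free replicate 2 was highest for Clps (0.771), St3gal4 (0.717) and Sycn (0.814). Sample gp130F/F germ-free replicate 4 was highest for the mean of the squamous list (0.858) and lowest for Adgre1 (0.788) and Ctsc (0.778). Sample gp130F/F germ-free replicate 5 was lowest for Chil4 (0.718) and Lrba (0.83). Of these, 6 each fell on gp130F/F SPF replicates 2 and 4.

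The genotype effect differed between germ-free and SPF mice, by the limma test of the difference itself, for 42 of the genes named here (adjusted p under 0.05 for each). It was higher in germ-free mice, with the log2 difference in parentheses, for Ccl27a (2.39), Cd248 (2.55), Col14a1 (2.58), Col15a1 (1.27), Col1a2 (1.08), Col3a1 (2.00), Eng (1.88), Esam (1.04), Fam183b (2.53), Fbln2 (2.12), Gfpt2 (2.25), Hic1 (2.14), Insm1 (2.09), Loxl1 (1.58), Lpl (3.60), Lyz2 (3.11), Mfap4 (2.17), Mfap5 (2.91), Nkx2-2 (1.62), Pdia2 (5.71), Pla2g1b (6.43), Plac9a (2.78), Plk1 (4.07), Scara5 (3.09), Sox18 (1.56), Sst (3.07), Tek (2.15) and Tppp3 (1.52). It was lower for Ccng2 (-3.36), Ciart (-2.66), Cma1 (-2.22), Cma2 (-2.12), Fcer1a (-2.70), Mcpt1 (-3.61), Mcpt4 (-2.26), Oas1g (-1.37), Rnase2a (-1.61), Sftpd (-2.54), Slc7a11 (-2.70), St3gal4 (-2.63), St3gal6 (-1.22) and Tpsb2 (-1.93). Ccng2, Fcer1a, Hic1, Mcpt4, Plac9a, Plk1, Rnase2a and Tpsb2 were undetected in at least 1 of the 4 groups, so that their values depend on the background and are no folds.

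In the BL6 wild-type arrays, which no comparison uses, 5 genes that no mixed-strain wild-type array detected were detected on all 3 arrays. Relative to the detection limit they were at least 106-fold higher for Adh7, 27.8-fold for Me1, 30.4-fold for Oit1, 17-fold for Plk1 and 4.97-fold for Gramd4. The fitted log2 signals, which depend on the background, differed by 7.95, 5.46, 5.42, 4.76 and 3.07 in that order.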

How the results depend on the processing

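The alternatives with sex, without the 4 arrays that stood apart (wild-type SPF replicates 1 and 2, gp130F/F SPF replicates 4 and 5) and with the corpus and pancreas markers as a covariate were chosen only after the result was seen. Counts are in the order SPF genotype (2290), germ-free genotype (314), housing in wild type (286), housing in gp130F/F (169) and difference (293). Counts not listed stayed within 1.5 times these, and the cause of the changes was not tested, except that a minimum fold change and fewer samples call fewer genes by construction. With a minimum fold change of 1.2 the counts were 632, 141, 29, 16 and 39. In a fit of only the 2 groups they were 1286 for SPF, 622 for wild type and 16 for gp130F/F. Array weights gave 591 for germ-free, 937 for wild type and 698 for the difference. With the BL6 arrays and a strain covariate the last 2 counts were 90 and 29, and with the BL6-labelled array counted as mixed, wild type had 183 and the difference 94. Median scaling gave 76 and 112 for the last 2, the stricter filter 258 for gp130F/F, and no filter and no background correction 148 and 167 for the difference. The corpus and pancreas covariate gave 1188 for SPF, 35 for gp130F/F and 41 for the difference, and 1075 SPF genes were called without the 4 arrays.

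Leaving out 1 array gave 1621 to 2933 and 217 to 385 genes for the genotype comparisons. Wild type had 72 to 466: 119, 149, 156 and 180 without SPF replicates 1, 2, 3 and 5, 91, 139, 72 and 111 without germ-free replicates 1 to 4, and 466 without gp130F/F SPF replicate 5. For gp130F/F it gave 61 to 720: 98, 720 and 80 without SPF replicates 3, 4 and 5, and 61, 85 and 75 without germ-free replicates 2, 3 and 5. The difference had 80 to 999: 145, 131 and 184 without wild-type SPF replicates 1, 2 and 5, 161 and 999 without gp130F/F SPF replicates 3 and 4, 121, 194, 81 and 80 without wild-type germ-free replicates 1 to 4, and 152, 190 and 148 without gp130F/F germ-free replicates 3, 4 and 5.

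With an estimated correlation 0, 1, 1, 0 and 0 lists were called, and the 7 germ-free lists became 3 to 10 with 1 array left out (4 without wild-type replicate 1, 3 without gp130F/F replicate 2). The smaller genotype effect in germ-free mice kept its direction and call in all alternatives run, which did not include array weights. With 1 array left out it was -0.296 to -0.133 for genes that rose and 0.242 to 0.447 for genes that fell. Without the 4 arrays the medians of the intestinal list in SPF mice and in wild type and of the squamous list in gp130F/F mice turned to -0.329, -0.122 and 0.0885.

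Of 6313 values of 182 named genes in a comparison under an alternative, 5618 kept direction and side of the threshold, 634 lost the call, 44 gained it and 17 turned, and the cause was not tested. In SPF mice Pnliprp1 and Rnase1 turned to 0.78 and 0.89 with the corpus and pancreas covariate. The other turns were of genes not called there. They were those of Il6st (0.07 with array weights, 0.31 without the 4 arrays, -0.19 to 0.04 with 1 array left out), of Il11 (-0.09 without background correction, -0.00 with array weights, -0.08 with the BL6 arrays, -0.01 with the covariate, -0.10 to 0.11 with 1 array left out), and of Reg3b (-0.75) and Reg3g (-0.29) without the 4 arrays. Signals near the background, as of Il11, limit what these arrays can show.

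Calls of named genes were lost in some of the 19 fits without 1 array, given as the number of fits and the highest adjusted p. In the SPF comparison they were Sprr2a1 16 (0.14), Pnliprp1 11 (0.11), Rnase1 5 (0.097), Chia1 4 (0.079), Junb 2 (0.059) and Ivl 1 (0.066). In the germ-free comparison they were Anxa8 7 (0.1) and Xlr4a 1 (0.05). In wild-type mice they were Fut4 15 (0.15), Clca4a 9 (0.1), Gsdmc2 8 (0.11), Mfap5 8 (0.12), St3gal4 8 (0.1), Muc5ac 7 (0.095), Ly6g6c 5 (0.078), Loxl1 4 (0.065), Ppfia3 2 (0.064), B3galt5 1 (0.053), Col1a2 1 (0.057) and Gfpt2 1 (0.055). In gp130F/F mice they were Dbp 6 (0.081), Esam 6 (0.081), Bach1 5 (0.081), Pdia2 5 (0.066), Pecam1 5 (0.067), Retnla 5 (0.089), Mptx1 4 (0.058), Cfap45 3 (0.068), Cfap69 3 (0.06), Robo4 3 (0.065) and Slurp1 1 (0.053). In the difference they were Eng 14 (0.1), Nkx2-2 14 (0.088), Sox18 13 (0.089), Pla2g1b 12 (0.088), St3gal4 12 (0.083), Pdia2 10 (0.082), Sst 10 (0.088), Scara5 9 (0.08), Slc7a11 9 (0.083), Sftpd 7 (0.072), Ccng2 5 (0.058), Lyz2 4 (0.064), Col14a1 3 (0.056), Esam 2 (0.056), Insm1 2 (0.057) and Tek 2 (0.059). Calls of the SPF comparison that were lost with a value moved by over 1.5 times were those of Chia1 (-2.33), Gcnt1 (0.92) and Ivl (1.69) without the 4 arrays, and of Pdia2 (-2.68), Sycn (-0.60), Hamp2 (-2.40), Junb (0.35), Clps (-1.41) and Cela1 (-0.29) with the corpus and pancreas covariate. With that covariate Pdia2 had 2.69 in gp130F/F mice, and Pdia2 and Pla2g1b 2.53 and 3.91 in the difference, and these calls were lost too.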

Other observations

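The tests below were chosen before the result was seen, apart from the choice of which lists to describe and from the values without the 4 arrays that stood apart and with the sex or the corpus and pancreas covariate. In gp130F/F SPF mice 6 of 34 intestinal genes rose and 0 fell (6 and 2 adjusted over the list alone; median 0.586, adjusted p = 0.0037, adjusted p = 0.67 with an estimated correlation). They included Clca1 (1.24 ± 0.25), Krt20, a keratin of surface epithelium (1.08 ± 0.14), Lgals4, a galectin (0.74 ± 0.09), and Pdx1, a transcription factor of antrum and duodenum (0.59 ± 0.14). The call was lost without the 4 arrays, where the median turned to -0.329 (adjusted p = 0.91), and without wild-type SPF replicate 1 (0.204, adjusted p = 0.071) and gp130F/F SPF replicate 4 (0.32, adjusted p = 0.085). The median was 0.323 without wild-type SPF replicate 2, 0.335 without gp130F/F SPF replicate 3 and 1.16 with the covariate of corpus and pancreas. In germ-free wild-type mice 2 intestinal genes rose, Clca1 (1.63 ± 0.26) and Spink4 (1.46 ± 0.25), and 0 fell (3 and 0 adjusted over the list alone). The size for Clca1 is not exact, as its germ-free mean, 15.75, lay near the highest normalized value, 16.02. The intestinal list had a median of 0.504 (camera, adjusted p = 0.0089, and adjusted p = 0.79 with an estimated correlation). That call too was lost without the 4 arrays, where the median turned to -0.122 (adjusted p = 0.85), without wild-type SPF replicates 1 and 2 (0.285 and 0.283, adjusted p = 0.17 and 0.14) and without wild-type germ-free replicate 2 (0.336, adjusted p = 0.087), and the median was 1.17 with the corpus and pancreas covariate. Of 51 proliferation genes, 4 fell in gp130F/F SPF mice (3 adjusted over the list alone; median -0.172, adjusted p = 0.021, adjusted p = 0.81 with an estimated correlation), among them Aurkb (-0.91) and Top2a (-0.85), which drive mitosis and DNA untangling, and Tyms (-0.72). This call was lost without the 4 arrays (adjusted p = 0.19), without wild-type SPF replicate 1 (-0.0931, adjusted p = 0.19) and without gp130F/F SPF replicates 2, 3 and 4 (-0.132, -0.102 and -0.107, adjusted p = 0.11, 0.13 and 0.13). The median was -0.319 without gp130F/F SPF replicate 1 and -0.383 with the corpus and pancreas covariate. In germ-free against SPF gp130F/F mice 4 rose (5 adjusted over the list alone; median 0.261, adjusted p = 0.00027, adjusted p = 0.74 with an estimated correlation), with Bub1b at 0.99, Aurkb at 0.93, Top2a at 0.84 and Plk1 named above. That median was 0.156 without gp130F/F SPF replicate 4 and 0.155 and 0.408 without gp130F/F germ-free replicates 1 and 3. Antimicrobial and acute phase genes did not pass as a list in SPF mice (adjusted p = 0.081), though Cfb (0.88 ± 0.21), Wfdc2 (0.85 ± 0.21) and Dmbt1 (0.61 ± 0.19) rose.

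Lists past the test and not described above were, in the SPF genotype comparison, circadian clock (median 0.331, adjusted p = 0.02, adjusted p = 0.22 with an estimated correlation). They further took in interferon response (0.219, 0.028, adjusted p = 0.71 with an estimated correlation), TGF-beta and SMAD targets (-0.199, 0.035, adjusted p = 0.22 with an estimated correlation) and MHC class II (-0.826, 0.035, adjusted p = 0.64 with an estimated correlation). Without the 4 arrays the calls of the clock (0.268, adjusted p = 0.064), interferon (0.157, adjusted p = 0.57) and TGF-beta lists (-0.146, adjusted p = 0.14) were lost, and with the corpus and pancreas covariate that of MHC class II (-0.306, adjusted p = 0.47), while the clock and interferon medians were 0.159 and 0.476. The clock call was lost without gp130F/F SPF replicate 4 (adjusted p = 0.085), and the interferon call without wild-type SPF replicates 1 and 3 (0.117 and 0.219, adjusted p = 0.21 and 0.055) and gp130F/F SPF replicates 3 and 4 (0.134 and 0.244, adjusted p = 0.26 and 0.05). The TGF-beta call was lost without wild-type SPF replicates 1 and 2 (adjusted p = 0.06 and 0.064) and gp130F/F SPF replicates 1 and 2 (adjusted p = 0.057 and 0.058). That of MHC class II was lost without wild-type SPF replicate 4 (adjusted p = 0.053) and gp130F/F SPF replicates 2 and 5 (-0.824 and -0.488, adjusted p = 0.06 and 0.13).

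In the germ-free genotype comparison they were complement and coagulation (0.224, 0.042, adjusted p = 0.87 with an estimated correlation) and liver (0.448, 0.043, adjusted p = 0.88 with an estimated correlation). The complement call was lost without gp130F/F SPF replicate 4 (adjusted p = 0.054), wild-type germ-free replicates 1, 3 and 4 (adjusted p = 0.058, 0.082 and 0.063) and gp130F/F germ-free replicates 2 and 3 (0.202 and 0.0742, adjusted p = 0.092 and 0.15), and with the corpus and pancreas covariate (0.166, adjusted p = 0.081). The liver call was lost without the same arrays (adjusted p = 0.054, 0.077, 0.082, 0.051, 0.092 and 0.073), without gp130F/F germ-free replicate 5 (adjusted p = 0.064), without the 4 arrays (adjusted p = 0.053) and with the covariate (0.117, adjusted p = 0.12). Its median was 0.271 without wild-type germ-free replicate 3. For housing in wild type they were endocrine cells (-0.666, 2.7e-05), enteric neurons and glia (-0.481, 0.0001), endothelium (-0.363, 0.0003), secretory stress (0.100, 0.021) and gland mucous cells (0.345, 0.043), each with adjusted p = 0.58 with an estimated correlation. With the corpus and pancreas covariate the endothelial (-0.243, adjusted p = 0.12) and secretory stress calls (0.104, adjusted p = 0.2) were lost, the latter also without wild-type germ-free replicate 3 (0.0836, adjusted p = 0.078). Without the 4 arrays the medians of endothelium and of enteric neurons and glia were -0.198 and -0.261, and the gland mucous call was lost (0.2, adjusted p = 0.37). It was lost too without wild-type SPF replicates 1 and 2 (0.217 and 0.239, adjusted p = 0.12 and 0.089), gp130F/F SPF replicate 4 (adjusted p = 0.052) and wild-type germ-free replicates 2 and 3 (0.249 and 0.197, adjusted p = 0.087 and 0.095).

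For housing in gp130F/F mice they were endocrine cells (0.657, 8.4e-07), mast cells (0.463, 0.00022) and macrophages (0.419, 0.00022), each with adjusted p = 0.46 with an estimated correlation. In the same mice they were also squamous genes (-1.08, 0.00033), enteric neurons and glia (0.413, 0.0074) and immediate early genes (-0.263, 0.01), each with adjusted p = 0.74 with an estimated correlation, and MHC class II (0.589, 0.0074, adjusted p = 0.70 with an estimated correlation). Without the 4 arrays the squamous median turned to 0.0885 (adjusted p = 0.73) and the call of immediate early genes was lost (-0.117, adjusted p = 0.26). The squamous call was also lost without gp130F/F SPF replicate 4 (-0.152, adjusted p = 0.29), that of immediate early genes without gp130F/F SPF replicate 5 (-0.122, adjusted p = 0.23), gp130F/F germ-free replicate 2 (adjusted p = 0.054) and with the corpus and pancreas covariate (-0.0134, adjusted p = 0.42). The neuron and glia call was lost without gp130F/F SPF replicates 3 and 5 (0.309 and 0.19, adjusted p = 0.053 and 0.077), and that of MHC class II without gp130F/F SPF replicate 5 (adjusted p = 0.051) and with the covariate (0.485, adjusted p = 0.094). The macrophage median was 0.629 without background correction and 0.228 with the covariate. For the difference between housing conditions they were smooth muscle (0.524, 4.2e-07, adjusted p = 0.52 with an estimated correlation), enteric neurons and glia (0.908, 3.7e-06) and macrophages (0.596, 3.7e-05), both with adjusted p = 0.29 with an estimated correlation. They were also mucin glycosylation (-0.400, 0.00012, adjusted p = 0.18 with an estimated correlation), circadian clock (-0.935, 0.00047, adjusted p = 0.15 with an estimated correlation), proliferation (0.208, 0.0062, adjusted p = 0.75 with an estimated correlation) and gland mucous cells (-0.383, 0.049, adjusted p = 0.62 with an estimated correlation). The proliferation call was lost without the 4 arrays (0.153, adjusted p = 0.083), without wild-type SPF replicate 1 (0.112, adjusted p = 0.076), gp130F/F SPF replicates 3 and 4 (0.103 and 0.147, adjusted p = 0.05 and 0.063), wild-type germ-free replicate 2 (0.0768, adjusted p = 0.087) and gp130F/F germ-free replicate 1 (0.0921, adjusted p = 0.091). Its median was 0.324 without wild-type SPF replicate 2, 0.33 without gp130F/F SPF replicate 1, 0.354 and 0.133 without gp130F/F germ-free replicates 3 and 5, and 0.461 with the corpus and pancreas covariate, with which the smooth muscle median was 0.937. The gland mucous call was lost without the 4 arrays (-0.109, adjusted p = 0.52), with sex as a covariate (adjusted p = 0.052) and in 10 of the 19 fits without 1 array. These were the fits without wild-type SPF replicates 1 and 2, gp130F/F SPF replicates 3 to 5, wild-type germ-free replicates 2 and 3 and gp130F/F germ-free replicates 3 to 5 (-0.284 to -0.392, adjusted p up to 0.11).

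The levels of Plk1 and Ccng2, which differed in 1 mixed-strain group, were read on the BL6 arrays too. Whether these levels followed housing or the line of mice was not tested. Plk1 stood at 9.06 ± 0.41 in mixed-strain gp130F/F germ-free mice (SD, n = 5), at 5.06 to 5.17 in the other mixed-strain groups, and at 9.14 to 10.30 in the BL6 groups. Ccng2 stood at 5.32 ± 0.07 in mixed-strain gp130F/F germ-free mice, at 8.33 to 9.07 in the other mixed-strain groups, and at 8.80 to 9.48 in the BL6 groups, which overlap the latter. The BL6-labelled gp130F/F germ-free sample whose title lacks BL6 had a Ccng2 level of 9.48, beyond the mixed-strain gp130F/F germ-free samples (5.26 to 5.42). The correlation between arrays did not single it out (0.9745 with its nearest array, against 0.966 for the array with the lowest such value).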
